A study of Mus musculus with 6 samples.

How the data were processed

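Liver RNA was measured on 6 one-colour Affymetrix arrays, 3 from C57BL/6 mice fed chow and 3 from mice fed a ketogenic diet. Per the labels, the mice were 8 weeks old at the start and were fed for 6 weeks, and the design text says that RNA of 2 to 3 animals per group was used. Whether 1 array held the RNA of 1 mouse or of a pool is not given in the sources used here, so p-values measure only the spread between these samples, which may in part be technical. Replicates were numbered within each diet in the order of deposition and pair no samples across diets.

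The deposited values are linear intensity per probe set, made by the authors with GCOS and MAS5 per the submitters' processing notes. The versions, the scaling target and the settings are not given in the sources used here. The table held 45101 probe sets, of which 64 were control probe sets. The arrays were not at a common level: the 2% trimmed mean signal was 53.5, 46.3 and 39.9 on chow arrays 1, 2 and 3, and 54.9, 61.0 and 45.8 on ketogenic arrays 1, 2 and 3. The design fixed before the data were examined kept the normalization as deposited, and this was kept, with other scalings beside it. Arrays give no read depth, and their number limits the precision.

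Signals were raised to a floor of 1.1, the 10th percentile of the table, and transformed to log2. Probe sets with a mean log2 signal at or above the median of 3.35 (signal 10.2) were kept, leaving 22515 without the controls. Gene symbols came from the platform annotation, in which 34958 probe sets had 1 symbol, 932 had several and 9211 were not listed. Of the symbols, 34754 matched a gene of the RefSeq table for assembly GRCm38.p6 and 0 changed by this match. The array's own build is not given, so no coordinates are printed. Each of 11866 genes was represented by its probe set with the highest mean log2 signal over all 6 arrays. Among the changed genes, 319 had several kept probe sets. Of these, 0 had another probe set past the threshold in the opposite direction, and 39 had a kept probe set of the opposite sign.

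Diets were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 4 residual and 5.07 prior degrees of freedom. Values are ketogenic minus chow on the log2 scale with the moderated standard error (SE), or mean signals with their SD (n = 3). A background of 10.8 was the mean over arrays, on the log2 scale, of the 95th percentile of 27 bacterial control probe sets. Where the mean log2 signal of 1 diet lay under it, signals under the background were raised to it on each array, and the change is given as at least the smaller of the ratios of means and of geometric means. Such a bound allows for the background only and not for the spread between arrays, so the true fold can be smaller. Single values per array were compared with a two-sided exact permutation test, whose smallest possible p for 3 against 3 arrays is 0.1.

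Before the data were examined, 33 gene lists were fixed, and 2 more of reference and sex-linked genes as checks. The lists covered de novo lipogenesis, cholesterol synthesis, mitochondrial and peroxisomal fatty acid oxidation, PPAR-alpha targets, ketone bodies, gluconeogenesis, glycolysis, the urea cycle and amino acid catabolism, ATF4 targets, endoplasmic reticulum chaperones, oxidative phosphorylation, bile acids, CAR and PXR targets, NRF2 targets, lipid storage, lipoproteins, the insulin and IGF axis, male-biased and female-biased genes, the clock, acute phase proteins, interferon-stimulated genes, proliferation and 9 cell types. They were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated per list, and with fry, whose directional test does not compare a list with other genes. Counts of members are given over all genes tested and adjusted over the list alone. A list's genes can belong to more than 1 list. List medians used fitted values. With means under the background raised to it, the median was 1.53 in place of 2.05 for proliferation and 1.26 in place of 1.56 for female-biased genes, and it moved by less in the other lists.

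Named genes followed a rule fixed beforehand. It took the 10 largest rises and 10 largest falls among changed genes whose diets did not overlap, up to 4 changed members of each metabolic list and up to 2 of each other list, or the brightest member where none changed. It also always took Scd1, Fasn, Acaca, Cpt1a, Pck1, Fgf21, Ppargc1a, Ppara, Srebf1 and Igf1. The rule's remaining always-named genes are not analysed here. Actb and the sex-linked genes served as checks.

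The fit and the list test were tested on simulated data for the 11866 genes, in 20 draws with 200 changed genes each. With variances drawn from the prior fitted to these arrays, 4.95% of the 2-fold and 76.7% of the 4-fold changes were recovered, and 5.33% of the calls were false. A first version used each gene's moderated variance. It recovered 15.7% and 93.7%, with 6.3% false calls, but its prior degrees of freedom were 8.2 against the 5.07 of the arrays, so the draws from the prior are the ones to read. A list of 22 genes shifted by 1 on the log2 scale was called in 20 of 20 draws. No list was called where no list effect was simulated, but the simulated genes were independent, so this says nothing about correlated genes. Alternatives covered scaling, floor, filter, variance model, array weights, probe set choice, list test and leaving out each array. Scaling to a common trimmed mean and to the 18 hybridization control probe sets was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.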

Results

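Livers of mice fed a ketogenic diet, which is very high in fat and very low in carbohydrate, were compared with livers of mice fed chow, a standard grain-based diet, to find which transcripts differ after 6 weeks. Gene expression was measured on 3 arrays per diet. The log2 signals correlated at 0.928 to 0.954 between arrays of the same diet and at 0.879 to 0.92 between diets. No 2 arrays held the same values. Array level overlapped between the diets: the 2% trimmed mean signal was 46.54 ± 6.8 (SD, n = 3) on chow and 53.91 ± 7.64 (SD, n = 3) on ketogenic arrays, with an exact permutation p = 0.3. Some control measures did not overlap. The hybridization controls, RNA of known amount added before hybridization, had a signal of 641.7 ± 8.53 (SD, n = 3) on chow and 499.5 ± 18.4 (SD, n = 3) on ketogenic arrays, with an exact permutation p = 0.1, the smallest possible. The ratio of 3' to 5' signal of actin, a sign of RNA integrity, was 2.08 ± 0.108 (SD, n = 3) on chow and 1.58 ± 0.0808 (SD, n = 3) on ketogenic arrays, with the same exact p = 0.1. The ratio for Gapdh was 0.839 ± 0.116 (SD, n = 3) on chow and 0.793 ± 0.0185 (SD, n = 3) on ketogenic arrays, with exact p = 0.9. For pyruvate carboxylase this ratio was 11.1 on chow array 3 and between 3.39 and 4.74 on the others.

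On the ketogenic diet, the transcript of Scd1, the main hepatic stearoyl-CoA desaturase, fell from a signal of 6466 ± 1492 to 104.1 ± 47.95 (SD, n = 3). Of 35 measured genes of the urea cycle and amino acid catabolism 14 fell (9 without chow array 1 and 7 without ketogenic array 3), among them Cps1, the entry enzyme of the urea cycle. For this list, adjusted p = 0.442 with an estimated correlation. Transcripts of Fgf21, a hormone secreted by the liver in fasting, rose from 24.57 ± 13.02 to 481.3 ± 96.19 (SD, n = 3). Of markers of macrophages 19 of 22 rose, and of matrix-producing stellate cells 15 of 20 (9 without chow array 2 or ketogenic array 3). For these lists, adjusted p = 0.29 and 0.442 with an estimated correlation. In limma's test, 877 of 11866 genes changed, 774 of them higher and 103 lower on the ketogenic diet, and 731 and 102 of these changed at least 2-fold. The smallest log2 change called was 0.882, so few smaller changes could be called and these shares follow largely from the test's power. At the level of probe sets 1045 of 22515 changed, 918 higher and 127 lower, with 633 and 649 changed without chow arrays 2 and 3 and 461, 441 and 330 without ketogenic arrays 1, 2 and 3. The diets did not overlap for 29.2% of the genes. Random groupings give 10% on average, but genes shift together between arrays, so 1 grouping can lie far from it. The share was not computed for other splits, so it does not measure chance.

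The split between rises and falls depended on how the arrays were scaled. As deposited, 88.3% of the changed genes were higher and the median log2 change of all genes was 0.235. With a common array median 917 genes were higher and 277 lower, with quantile normalization 578 and 326, and with a common trimmed mean 676 and 361, or 76.8%, 63.9% and 65.2% higher. These scalings moved the median of all genes by -0.112, -0.243 and -0.213. Scaling to the hybridization controls moved it by 0.362 and gave 3818 higher and 93 lower. With quantile normalization 514 of the 774 rises and 97 of the 103 falls remained past the threshold. Without chow array 3 565 genes passed, and without ketogenic arrays 1, 2 and 3 555, 580 and 526. Rises numbered 515 and 497 without chow arrays 2 and 3 and 451, 437 and 466 without ketogenic arrays 1, 2 and 3, and falls 67, 68 and 60 without chow array 1, chow array 3 and ketogenic array 3. Ranges over the scalings cover the deposited values and these 4 scalings. Among the 73 changed genes named here, the diets overlapped only for Marco. Of 37 further probe sets of 27 of these genes, all 37 had the sign of the representative one, 24 passed the threshold and 13, of 8 genes, did not. Dim probe sets of Pck2, Mcm6 and Coro1a that the filter left out had log2 changes of 0.25, 0.41 and -1.13.

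**Figure D1:**
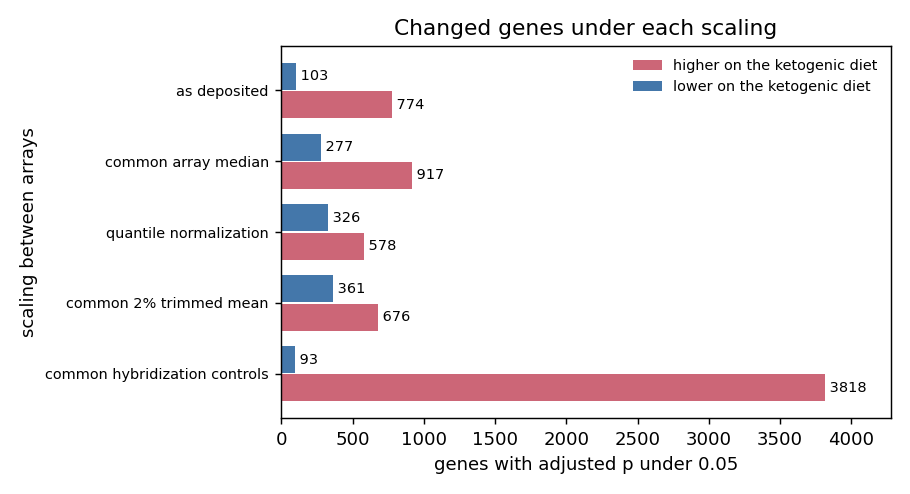
Number of genes past an adjusted p of 0.05 that were higher (red) or lower (blue) on the ketogenic diet, for the values as deposited and 4 scalings. Falls ranged from 93 to 361 and rises from 578 to 3818.

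The largest rises were of transcripts that lay under or near the background on chow. Mmp12, a macrophage elastase, rose at least 11.9-fold, Cbr3, a carbonyl reductase, at least 30.3-fold, and Tnfrsf12a, a receptor of the tumour necrosis factor family, at least 15.2-fold. Gpnmb and Lgals3, both abundant in lipid-laden macrophages, rose, Gpnmb at least 12.4-fold and Lgals3 by 4.58 ± 0.27 (log2, SE) with adjusted p = 0.000108. Ifi27l2b rose at least 9.86-fold and Psat1, an enzyme of serine synthesis, at least 9.52-fold. Rad51b rose at least 20.2-fold on its representative probe set, while its other, dimmer probe set changed by 0.33. Lcn2, which encodes lipocalin 2, rose at least 10.8-fold. Its call was lost under 9 of 18 alternatives (adjusted p up to 0.218), among them without chow array 1 or ketogenic array 2 or 3 (0.0661, 0.0594 and 0.0956), with a common array median (0.0552), with a common trimmed mean (0.0616) and with quantile normalization (0.073). The largest falls were those of Hsd3b5, a male-specific hepatic steroid dehydrogenase, which fell at least 81.1-fold, Scd1 and Nnmt, nicotinamide N-methyltransferase, whose signal fell from 842.3 ± 310.5 to 26.77 ± 11.68 (SD, n = 3). Thrsp, Upp2, Ces2a, Susd4 and Ugt2b38 followed, with log2 changes of -3.42, -3.15, -2.93, -2.83 and -2.79, and Hydin fell at least 3.44-fold. Upp2 was not past the threshold under 4 of 19 alternatives (adjusted p up to 0.179), among them without chow array 1 (0.0511) and with a trended robust prior (0.0958). Dct fell at least 5.02-fold. That call was lost under 11 of 18 alternatives (adjusted p up to 0.259), among them when any 1 chow array was left out (between 0.0758 and 0.123), with a common array median (0.0592), with a common trimmed mean (0.0613) and with quantile normalization (0.07).

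**Figure D2:**
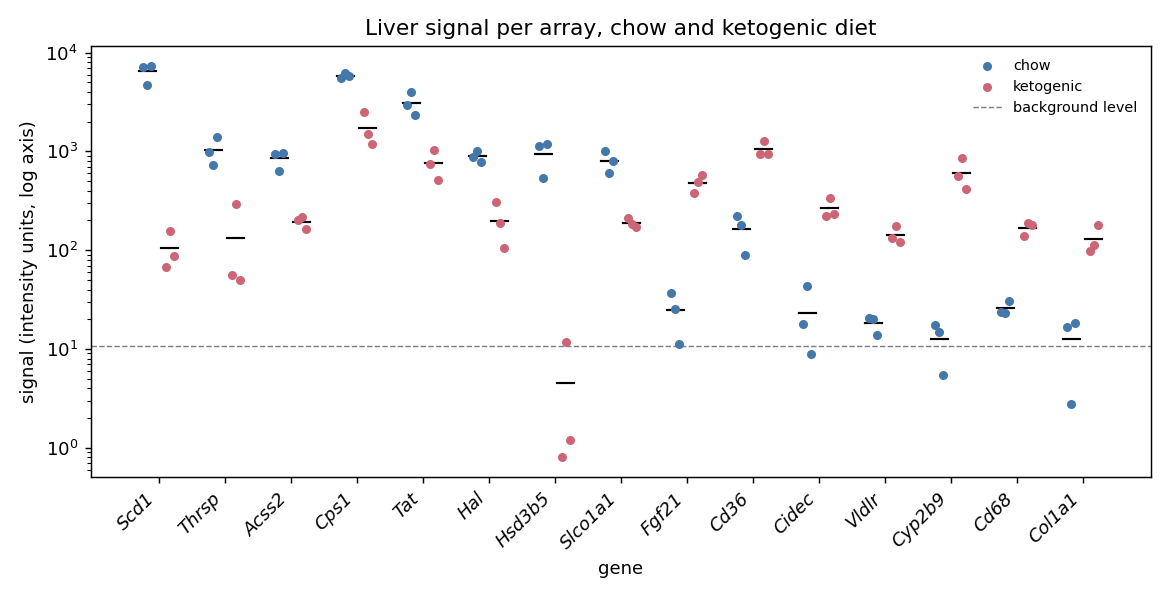
Signal (log axis) of 15 named genes on each of the 3 chow (blue) and 3 ketogenic (red) arrays, with group means as black bars and the background of 10.8 as a dashed line. Scd1 had a mean of 6466 on chow and 104.1 on the ketogenic diet, and Fgf21 24.57 and 481.3.

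Of 22 measured genes of de novo lipogenesis, 3 fell and 1 rose (5 and 1 adjusted over the list alone), and over the scalings 3 to 7 fell and 0 to 3 rose. Scd1 fell by 6.02 ± 0.35 (log2, SE), with adjusted p = 0.000108. Thrsp, a lipogenic regulator, fell by 3.42, a call lost under 4 of 19 alternatives (adjusted p up to 0.165), among them without ketogenic array 3 (0.0532) and with a trended robust prior (0.0798). Acss2, which activates acetate, had a log2 change of -2.12 (adjusted p = 0.00305). Scd2, a desaturase with little expression in adult liver, rose by 1.28 on its representative probe set, while another had a log2 change of 0.27 (adjusted p = 0.627). The call of Scd2 was lost with quantile normalization (0.0543) and with the mean of its probe sets (0.0956), in a range from 0.00172 over the alternatives. Fatty acid synthase, Fasn, had a log2 change of -1.11 ± 0.31 (SE), with adjusted p = 0.0657, and passed the threshold under 5 of 19 alternatives. Acaca, acetyl-CoA carboxylase, changed by -0.02 and the regulator Srebf1 by -0.42, neither past the threshold. As a group the list was lower in camera (adjusted p = 6.13e-06), and adjusted p = 0.475 with an estimated correlation. Its median was -0.288 and became 0.0743 when scaled to the hybridization controls. In cholesterol synthesis and uptake, 1 of 20 genes fell (1 adjusted over the list alone), namely Tm7sf2, a sterol reductase, with a log2 change of -1.51. That call was lost without chow array 1 or 2 or ketogenic array 1 or 3 (adjusted p between 0.0527 and 0.0776). The cholesterol list's median was -0.49 with camera adjusted p = 1.57e-08, and adjusted p = 0.475 with an estimated correlation. Its median became -0.129 when scaled to the hybridization controls. With a common array median 6 of its genes fell, and over the scalings 1 to 6 fell and 0 or 1 rose.

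Of 19 measured targets of PPAR-alpha, the nuclear receptor of fasting and fatty acids, 7 rose and 0 fell (8 and 0 adjusted over the list alone), and over the scalings 6 to 11 rose. Fgf21 rose by 4.44 ± 0.42 (log2, SE), with adjusted p = 0.000793, and Cd36, a fatty acid transporter, by 2.77. Cidec, a lipid droplet protein, rose by 3.77, and Fabp3 rose at least 7.25-fold on its representative probe set. Another probe set of Fabp3 had a log2 change of 0.33 (adjusted p = 0.726), and its call was lost with a trended robust prior (0.0529, in a range from 0.00208 to 0.181). The list was higher with camera adjusted p = 0.000216, and adjusted p = 0.475 with an estimated correlation. Of 23 genes of triglyceride storage, 9 rose (13 adjusted over the list alone, and 9 to 14 over the scalings), among them Vldlr, a lipoprotein receptor, by 2.97 and Plin4 by 2.97. Another probe set of Vldlr had a log2 change of 2.07 (adjusted p = 0.211), and its call was lost without probe sets that can bind several transcripts (0.175, the highest of its alternatives, in a range from 2.83e-12). That of Plin4 was lost under 10 of 18 alternatives (adjusted p up to 0.199), among them without chow array 1 or 3 or ketogenic array 2 or 3 (between 0.0533 and 0.0864), with a common array median (0.0502), with a common trimmed mean (0.0569) and with quantile normalization (0.0717). For this list camera gave adjusted p = 5.12e-05, and adjusted p = 0.475 with an estimated correlation. Ppara itself had a log2 change of 0.25 and the coactivator Ppargc1a one of -0.13, neither past the threshold.

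No gene of mitochondrial fatty acid oxidation passed the threshold in limma (0 of 19, also adjusted over the list alone), 5 were higher at an unadjusted p under 0.05, and all 19 had a positive log2 change with a median of 0.44 against 0.235 for all genes. Scaled to the hybridization controls 12 of the 19 rose, and with quantile normalization 1. The camera test gave adjusted p = 0.0873 as deposited, 0.000174 with quantile normalization, 0.0474 with hybridization control scaling and 0.0141 without chow array 2, passed the threshold under 5 of 21 alternatives and ranged up to 0.709. Hadh, its brightest member, had a log2 change of 0.33 and Cpt1a, the gatekeeper of mitochondrial fatty acid import, one of 0.69 ± 0.32 (SE), with adjusted p = 0.234. On its other probe sets the log2 change of Cpt1a was -0.21 and -0.03, and with the mean of its probe sets 0.15. Hadh and Cpt1a passed the threshold only when scaled to the hybridization controls (adjusted p = 0.0334 and 0.0317, in ranges up to 0.722 and 0.836). Of 19 genes of peroxisomal and microsomal oxidation, 2 rose (7 rose and 2 fell adjusted over the list alone), Aldh3a2, a fatty aldehyde dehydrogenase, by 1.61 and Abcd2, a peroxisomal transporter, by 3.03. Scaled to the hybridization controls 10 of the 19 rose, without chow array 2 5, and without any 1 ketogenic array 1, and 1 fell with each of the 3 other scalings. The call of Abcd2 was lost under 9 of 19 alternatives (adjusted p up to 0.246), among them when any 1 ketogenic array was left out (between 0.0662 and 0.101), with a common array median (0.0637), with a common trimmed mean (0.0692) and with quantile normalization (0.0877). The peroxisomal list had camera adjusted p = 0.149 as deposited, 0.006 with quantile normalization and 0.00377 without chow array 2, passed the threshold under 4 of 21 alternatives and ranged up to 0.709. Of 7 measured genes of ketone body metabolism, Bdh1, which makes beta-hydroxybutyrate, rose by 1.55 and Oxct1, which uses ketone bodies, by 1.69, while Bdh2 fell by 1.83 (4 rose and 1 fell adjusted over the list alone, and 1 to 5 rose over the scalings). The call of Bdh1 was lost without chow array 2 or 3 or ketogenic array 1 or 2 (adjusted p between 0.0513 and 0.0612), and that of Oxct1 without chow array 2 or 3 or ketogenic array 3 (0.0543 to 0.0745), with a common trimmed mean (0.0512), with quantile normalization (0.0552) and without probe sets that can bind several transcripts (0.0822). These calls were lost under 6 of 19 and 8 of 18 alternatives (adjusted p up to 0.138 and 0.158), and another probe set of Oxct1 had a log2 change of 1.47 (adjusted p = 0.106). As a group the list was not called (camera adjusted p = 0.313).

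In gluconeogenesis, 2 of 15 genes fell and 1 rose (2 and 1 adjusted over the list alone), over the scalings 1 to 4 fell, without ketogenic array 3 0, and without any 1 other array except ketogenic array 2 1. G6pc, the glucose-6-phosphatase, fell by 1.04, a call lost when any 1 array except ketogenic array 2 was left out (adjusted p between 0.0552 and 0.15) and when scaled to the hybridization controls (0.0512). Got1, an aspartate aminotransferase, fell by 2.40, a call lost without ketogenic array 3 (0.0775) and with a trended robust prior (0.0551), in a range up to 0.176. Pck2, the mitochondrial PEP carboxykinase, rose at least 6.13-fold, while the cytosolic enzyme Pck1 had a log2 change of -0.82 ± 0.38 (SE) with adjusted p = 0.237, and passed under 2 of 19 alternatives (0.0383 to 0.467). The gluconeogenesis list was lower with camera adjusted p = 0.000522, and adjusted p = 0.475 with an estimated correlation. In glycolysis, 1 of 15 genes rose (1 adjusted over the list alone), Aldoa by 1.09, and 7 when scaled to the hybridization controls. With each of the 3 other scalings 1 fell. The call of Aldoa was lost when any 1 of the 6 arrays was left out (adjusted p between 0.0597 and 0.138) and with the mean of its probe sets (0.0785), in a range up to 0.154. Its 4 other probe sets had log2 changes of 0.67 to 1.30 and did not pass (adjusted p between 0.0578 and 0.208). The glycolysis list was not called (camera adjusted p = 0.535).

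Of 35 measured genes of the urea cycle and amino acid catabolism 14 fell and 0 rose (18 and 0 adjusted over the list alone), and 33 had a negative log2 change. Without chow array 1 and ketogenic array 3 9 and 7 fell. Cps1 fell from 5836 ± 411.9 to 1730 ± 678.9 (SD, n = 3), with adjusted p = 0.00925. Hal, which degrades histidine, fell by 2.29, and Tat, which degrades tyrosine, by 2.03. This list was lower with camera adjusted p = 6.09e-23, and adjusted p = 0.442 with an estimated correlation. With a common array median 21 of its genes fell, and over the scalings 13 to 23. Of 24 targets of ATF4, the transcription factor of the amino acid response, 14 rose and 1 fell (17 and 1 adjusted over the list alone), over the scalings 11 to 19 rose, and without chow array 3 and ketogenic array 2 8 and 9. The fall was that of Cth, named after its values were seen (log2 change -1.19, adjusted p = 0.0478), and was lost, among others, when any 1 array was left out and when scaled to the hybridization controls. Nupr1 rose at least 5.91-fold, Aldh18a1, of proline synthesis, at least 6.65-fold and Atf3 at least 5.29-fold. The call of Atf3 was lost without ketogenic array 3 (adjusted p = 0.0621), with a common trimmed mean (0.0558) and with quantile normalization (0.0602), in a range up to 0.169. Of the 4 other probe sets of Aldh18a1 3 did not pass, with log2 changes of 2.37, 1.41 and 0.52 (adjusted p = 0.107, 0.0905 and 0.56). Its call was lost without probe sets that can bind several transcripts (0.0822, the highest of its alternatives, in a range from 3.55e-07). The ATF4 list was higher with camera adjusted p = 5.91e-08, and adjusted p = 0.475 with an estimated correlation. Of 18 endoplasmic reticulum chaperones 0 passed the threshold of limma (0 adjusted over the list alone and 0 at an unadjusted p under 0.05), and Hspa5 had a log2 change of -0.25. The chaperone list's median was -0.067, and 0.295 when scaled to the hybridization controls. Its camera adjusted p = 0.0531 for a lower list went to 0.0197 with a common array median, 0.0139 with a common trimmed mean and 0.0183 without ketogenic array 2, passed the threshold under 5 of 21 alternatives and ranged up to 0.945.

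Of 22 targets of NRF2, the regulator of oxidative defence, 7 rose and 0 fell (12 and 0 adjusted over the list alone), and over the scalings 7 to 15 rose. Hmox1, heme oxygenase, rose by 2.05, Srxn1 by 2.05, Gstm3 by 1.85 and Osgin1 by 1.82, while 1 of 3 other probe sets of Srxn1 had a log2 change of 0.79 (adjusted p = 0.378). The list had camera adjusted p = 0.00103, and adjusted p = 0.475 with an estimated correlation. Of 33 genes of oxidative phosphorylation 0 passed in limma (0 adjusted over the list alone and 0 at an unadjusted p under 0.05), and the brightest, Uqcrb, had a log2 change of -0.28. With a common trimmed mean 3 of them fell and with a common array median 1. Their median was -0.116 with camera adjusted p = 0.000132, and adjusted p = 0.615 with an estimated correlation. It became 0.246 when scaled to the hybridization controls.

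In bile acid synthesis and transport, 2 of 20 genes fell and 1 rose (6 and 1 adjusted over the list alone), over the scalings 2 to 7 fell, and without ketogenic array 3 1. Slco1a1, an organic anion transporter, fell by 2.07, and Cyp7b1, of the alternative bile acid pathway, had a log2 change of -1.66, a call lost without ketogenic array 3 (adjusted p = 0.0518). Abcb4, the phospholipid exporter, rose by 1.27, a call lost when chow array 3 or any 1 ketogenic array was left out (0.0591 to 0.0785). The bile acid list was lower with camera adjusted p = 6.13e-06, and adjusted p = 0.475 with an estimated correlation. Its median of -0.234 became 0.127 when scaled to the hybridization controls. Among 22 targets of CAR and PXR, nuclear receptors of foreign compounds, 6 fell and 3 rose (7 and 3 adjusted over the list alone), over the scalings 5 or 6 fell and 3 to 5 rose, and 3 fell without chow array 3 or ketogenic array 3. Ces2a, a carboxylesterase, fell by 2.93, while Cyp2b9 rose from 12.5 ± 6.295 to 611.2 ± 220.6 (SD, n = 3), Cyp2b13 rose at least 6.0-fold and Abcc4, an efflux pump, rose by 2.55. The CAR and PXR list was lower with camera adjusted p = 0.00102, and adjusted p = 0.475 with an estimated correlation. With quantile normalization its adjusted p was 0.0774, in a range from 5.85e-06 to 0.711 over the alternatives, and the median of -0.326 became 0.0359 when scaled to the hybridization controls.

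Of 14 genes with a male bias in mouse liver 7 fell (13 adjusted over the list alone) and all 14 had a negative log2 change, including Hsd3b5 and Slco1a1. Over the scalings 6 to 11 fell, without chow array 1, chow array 3 or ketogenic array 2 4, and without ketogenic array 3 3. The male-biased list had camera adjusted p = 7.92e-17, and adjusted p = 0.29 with an estimated correlation. Of 12 female-biased genes past the filter, from a list of 24, 4 rose (5 adjusted over the list alone, and 3 to 6 over the scalings), including Cyp2b9 and Cyp2b13. For this list camera gave adjusted p = 0.0237, and adjusted p = 0.475 with an estimated correlation. The female-biased call ended without chow array 1 or without ketogenic array 3 (adjusted p = 0.0781 in each), with no filter (0.321), with the ordinary t statistic (0.179), with array weights (0.112) and when scaled to the hybridization controls (0.256). Its adjusted p ranged from 3.17e-07 to 0.475. With no filter the list's median was 0.631 in place of 1.56. The filter used the mean over both diets, so a gene dim on chow could pass it through its ketogenic signal. The Y-linked gene Eif2s3y had a signal between 60.5 and 133.8 on all 6 arrays on its brightest probe set, and Xist, expressed from the inactive X chromosome of females, one between 9.5 and 26.8 on its brightest probe set.

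Of 22 macrophage and Kupffer cell markers 19 rose (19 adjusted over the list alone), among them Cd68 by 2.71 ± 0.25 (log2, SE), with adjusted p = 0.000693. Marco, for which the diets overlapped, had a mean at least 6.7-fold higher by the bound from the background. In limma, the 95% confidence interval of its log2 change was 1.6 to 5.75. Its call was lost under 10 of 18 alternatives (adjusted p up to 0.256), among them without chow array 2 or 3 or ketogenic array 1 or 2 (between 0.0717 and 0.14), with a common array median (0.0628), with a common trimmed mean (0.0729) and with quantile normalization (0.0827). Of 20 stellate cell and matrix genes 15 rose (17 adjusted over the list alone), over the scalings 10 to 18, and without chow array 2 or ketogenic array 3 9, with Col1a1, a fibrillar collagen, at least 8.5-fold and Col5a2 at least 5.33-fold higher, both lost without ketogenic array 3 (adjusted p = 0.0536 and 0.0573). The call of Col5a2 was also lost with a common trimmed mean (0.051) and with quantile normalization (0.0515), in a range up to 0.165. The macrophage list had camera adjusted p = 2.84e-15, and adjusted p = 0.29 with an estimated correlation. For the matrix list camera gave adjusted p = 7.55e-11, and adjusted p = 0.442 with an estimated correlation. Of 15 proliferation genes past the filter, from a list of 25, 9 rose (13 adjusted over the list alone), with Mcm6 at least 6.49-fold and Mki67 at least 2.9-fold higher. Of the 15, 6 had a mean under the background in at least 1 diet. The proliferation list had camera adjusted p = 7.96e-09, and adjusted p = 0.29 with an estimated correlation. Of 20 interferon-stimulated genes 4 rose (8 adjusted over the list alone), and 16 when scaled to the hybridization controls and 6 with a common array median or trimmed mean, while 1 fell with quantile normalization. The 4 included Cxcl10, at least 5.01-fold, and Ifi27l2a, by 2.77, the latter at adjusted p = 0.05 without ketogenic array 3. The interferon list had camera adjusted p = 9.08e-05, and adjusted p = 0.475 with an estimated correlation. On the same arrays the actin 3' to 5' ratio was 2.08 on chow and 1.58 on the ketogenic diet, the Gapdh ratio was 0.839 and 0.793, and the median of 19 hepatocyte identity genes changed by -0.174.

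Of 17 liver endothelial markers 2 rose (4 adjusted over the list alone), Tek by 1.19 and Eng by 1.08. Scaled to the hybridization controls 9 of the 17 rose, with a common array median 4, without chow array 1 4, and without any 1 other array 0. Both calls were lost when any 1 array except chow array 1 was left out (adjusted p between 0.0508 and 0.0935 for Tek, 0.0746 and 0.104 for Eng), and that of Eng with the mean of its probe sets (0.0914), another of which had a log2 change of 0.52 (adjusted p = 0.317). The endothelial list had camera adjusted p = 0.0527, which went to 0.0349 with a common array median, 0.0151 without chow array 1 and 0.0466 without ketogenic array 3, passed the threshold under 9 of 21 alternatives and ranged from 0.00267 to 0.709. Of 10 lymphocyte markers past the filter, from a list of 23, 3 rose (3 adjusted over the list alone). Coro1a was at least 6.72-fold higher and Ptprc, the pan-leukocyte antigen, was higher by 2.25. The lymphocyte list had camera adjusted p = 0.0467, and adjusted p = 0.475 with an estimated correlation. This call, whose adjusted p ranged from 0.00542 to 0.475 and which was lost under 11 of 20 alternatives, ended among others with a common array median (0.0763), a common trimmed mean (0.0567) or hybridization control scaling (0.131), and without chow array 1 (0.139), chow array 3 (0.0684) or ketogenic array 2 (0.107). Of 7 cholangiocyte markers past the filter, from a list of 14, 2 rose (3 adjusted over the list alone, and 1 to 4 over the scalings). These were Krt23, at least 6.01-fold, and Aqp1, by 0.98. The call of Aqp1 was lost under 11 of 19 alternatives, among them when any 1 array except chow array 1 was left out (adjusted p between 0.109 and 0.161), with a common trimmed mean (0.0623) and with quantile normalization (0.0674). The cholangiocyte list had camera adjusted p = 0.0245, and adjusted p = 0.475 with an estimated correlation. Its call ended without chow array 2 (0.0565) or ketogenic array 3 (0.127), with the ordinary t statistic (0.0549) and with hybridization control scaling (0.0828), in a range from 0.00409 to 0.475. Of 6 blood genes past the filter, from a list of 15, 2 rose and 1 fell (2 and 1 adjusted over the list alone). The fall, that of Alas2, named after its values were seen (log2 change -1.01, adjusted p = 0.049), was lost, among others, when any 1 array was left out and when scaled to the hybridization controls, where 3 rose. The rises were those of the neutrophil genes S100a8 and S100a9, at least 2.5-fold and 2.41-fold. Camera gave adjusted p = 0.254 for the blood list, while fry called it higher (adjusted p = 0.00677), the only 1 of 19 alternatives to do so, in a range up to 0.686. Of 7 adipocyte genes past the filter, from a list of 16, 4 rose (4 adjusted over the list alone), Lpl by 2.20. Camera gave adjusted p = 0.0518 for the adipocyte list, which went to 0.0317, 0.0436 and 0.04 without chow arrays 1, 2 and 3 and 0.00415 without ketogenic array 1. It passed the threshold under 8 of 20 alternatives and ranged up to 0.699. Of these 7 genes 5 are also in another list. With no filter the adipocyte list's median was 0.523 in place of 1.4 (camera adjusted p = 0.0368). As for the female-biased genes, a gene dim on chow could pass the filter through its ketogenic signal. Of 7 exocrine pancreas genes past the filter, from a list of 21, 0 passed in limma. Adjusted over the list alone 1 fell, and 1 was lower at an unadjusted p under 0.05. Cela1 had a log2 change of -0.95, past the threshold under 6 of 19 alternatives (adjusted p from 0.00596 to 0.165). In this list 1 gene fell with a common array median, a common trimmed mean or quantile normalization. The pancreas list had camera adjusted p = 0.0621, which went to 0.00703 without chow array 2, 0.0395 without ketogenic array 1 and 0.0243 when scaled to the hybridization controls, where its median of -0.0861 became 0.276, in a range up to 0.709. Of 19 hepatocyte identity genes 0 passed in limma (0 adjusted over the list alone and 0 at an unadjusted p under 0.05), and albumin, Alb, changed by -0.01. Its signal, between 7779.8 and 8417, lay near the highest of each array (9772.8 to 10485.9), where a change could be missed. The hepatocyte list was lower with camera adjusted p = 0.00096, and adjusted p = 0.475 with an estimated correlation. That call ended with quantile normalization (0.086, in a range from 2.63e-05 to 0.475), and the list's median of -0.174 became 0.188 when scaled to the hybridization controls.

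**Figure D3:**
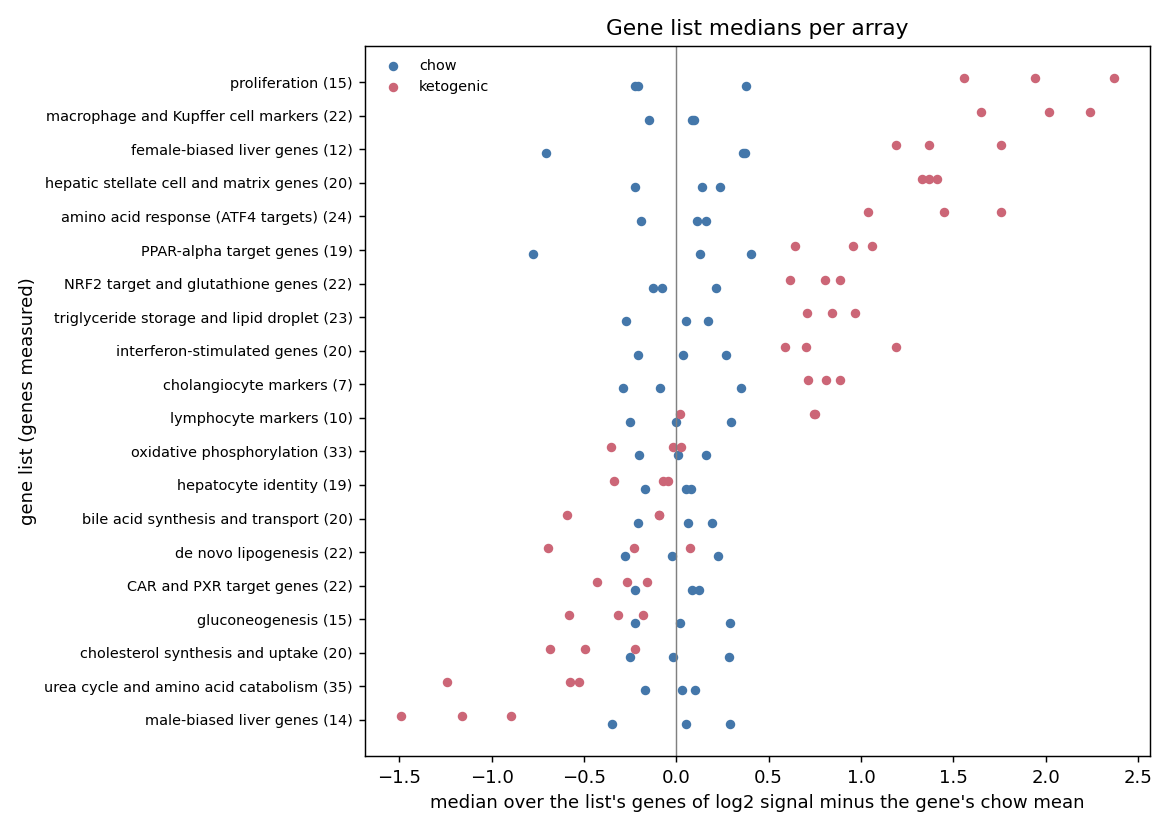
Median over each list's genes of the log2 signal minus the gene's chow mean, for each chow (blue) and ketogenic (red) array, for the 20 lists called by camera at the preset correlation, with the number of genes measured. Macrophage markers sat between 1.65 and 2.24 on the ketogenic arrays and between -0.15 and 0.0971 on the chow arrays, while the medians of the lipogenesis, bile acid, CAR and PXR, oxidative phosphorylation and hepatocyte lists turned positive under hybridization control scaling.

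Among the remaining lists, 1 of 18 lipoprotein genes rose (1 adjusted over the list alone), Apoa4 by 2.54 (a call lost with a trended robust prior, adjusted p = 0.0537, in a range up to 0.15), and 1 of 21 genes of the insulin and IGF axis (3 rose and 1 fell adjusted over the list alone), Igfbp1, an insulin-repressed binding protein, by 2.21. Over the scalings 1 to 3 lipoprotein genes and 1 to 6 genes of the insulin and IGF axis rose, and 0 to 3 of the latter fell, with 2 falls without ketogenic array 2. Igf1 had a log2 change of -0.56 ± 0.26 (SE), with adjusted p = 0.237, and passed with a common array median (0.0494) and a common trimmed mean (0.0262), in a range up to 0.498. Of 23 acute phase genes 4 rose and 2 fell (6 and 2 adjusted over the list alone), over the scalings 1 to 6 rose, and without chow array 3 and ketogenic arrays 1, 2 and 3 2, 2, 1 and 0, with Lcn2 higher and Orm1, an orosomucoid, lower with a log2 change of -1.83. Of 18 clock genes 0 passed in limma (0 adjusted over the list alone, and 1 higher and 2 lower at an unadjusted p under 0.05), and Nr1d2 had a log2 change of 0.43. Clock genes passed elsewhere: 2 rose when scaled to the hybridization controls, 1 rose and 1 fell with a common array median, 1 fell with quantile normalization, 2 fell with a common trimmed mean and 1 rose without chow array 1. Camera gave adjusted p = 0.313, 0.175, 0.23 and 0.23 for lipoproteins, insulin and IGF, acute phase and clock, with a lower direction in each. The acute phase list was called without probe sets that can bind several transcripts (0.0219, in a range up to 0.709). The mean log2 change was positive for all 4 lists and the median positive for acute phase and clock. With a common array median the medians of acute phase and clock were -0.00767 and -0.00487, and under hybridization control scaling those of lipoproteins and of insulin and IGF were 0.337 and 0.295. Of 11 reference genes 0 passed in limma, with 2 at an unadjusted p under 0.05 and log2 changes between -0.37 and 0.87. Actb had a log2 change of 0.27 on its representative probe set and -0.52 on another, neither past the threshold, and passed when scaled to the hybridization controls (adjusted p = 0.0435, in a range up to 0.863).

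Of the 33 lists, 20 were called by camera at the preset correlation, 11 higher and 9 lower, 0 with an estimated correlation (smallest adjusted p = 0.29, and 3 lists at an unadjusted p under 0.05) and 14 by fry. Fry called all 11 higher lists, but of the 9 lower ones only the urea cycle (adjusted p = 0.0386) and male-biased lists (0.021). For the remaining lower lists fry gave adjusted p between 0.2 and 0.711. Lower in camera means lower relative to the other genes, and the median log2 change of all genes was 0.235. At the preset correlation the other 9 ways to split the 6 arrays into 3 and 3 called between 6 and 16 lists. These splits mix the diets and keep part of the diet difference, so their calls are not those of groups without a difference.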

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

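The tests of explanations in this part, their bounds, and the scalings to a trimmed mean and to the hybridization controls were chosen after the results were seen, and the bounds on list medians were reworded, once their values were known, to cover each array left out. With an earlier wording of the bound for the female-biased genes, on the medians with all arrays, array level was argued against for them too. A signal outside the comparisons was found in the control probe set at the 5' end of actin, which lay at 1741 ± 199 on chow and 3265 ± 146 on ketogenic arrays (SD, n = 3), 1.88 times higher, with an exact permutation p = 0.1, the smallest possible. Among probe sets without a single gene symbol, which the gene comparisons did not use, 74 rose and 22 fell.

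Among the changed genes 88.3% were higher on the ketogenic diet. Brighter hybridization or staining of the ketogenic arrays that raises controls and other probe sets alike is argued against, since the hybridization controls changed by -22.2% on them. The scaling of the deposited values is not given, so the raw brightness of the arrays is not known. Differences in array level as the whole cause cannot be told apart from the diet: with quantile normalization or a common trimmed mean the share was 63.9% or 65.2%, and as low as 60.9% with an array left out, above a bound of 60% by less than its SD of 6.16. The diet itself stays open as an untested explanation.

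Of 22 macrophage and 20 matrix markers 19 and 15 rose (for matrix 9 without chow array 2 or ketogenic array 3, and for the lists adjusted p = 0.29 and 0.442 with an estimated correlation), with Lyz2 at a mean signal of 124.7 on chow and 801.7 on the ketogenic diet and Col3a1 at 106.2 and 808. A difference in array level is argued against, as the lower of the list medians was still 0.986 under the scaling and without the array that lowered it most (largest SD over arrays left out 0.134). A lower share of hepatocytes as the whole cause, with other cell types unchanged, would raise all other markers alike, and is argued against. The macrophage and matrix medians minus the endothelial median were higher on every ketogenic than on every chow array, with a smallest gap of 0.47. A lower share as part of the cause is left open. As deposited, the endothelial, cholangiocyte and lymphocyte medians were 0.366, 0.752 and 0.556, and that of hepatocyte identity genes was -0.174. RNA integrity cannot be told apart from the diet, since the actin 3' to 5' ratio on ketogenic arrays was 0.762 of that on chow without overlap, while the Gapdh ratio was 0.839 on chow and 0.793 on ketogenic arrays and overlapped (exact p = 0.9). More macrophages and stellate cells, or a change in their state, may contribute and was not tested.

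Of 14 male-biased genes 7 fell (4 without chow array 1, chow array 3 or ketogenic array 2, and 3 without ketogenic array 3) and of 12 female-biased genes 4 rose (for the lists, adjusted p = 0.29 and 0.475 with an estimated correlation), and the female-biased call was lost under 7 of 21 alternatives. Female samples are argued against, since the lowest Eif2s3y signal on a ketogenic array was 60.5, against a background of 10.8, which leaves a mix-up of male samples untested. Array level as the cause is argued against for the male-biased genes, whose median nearest to 0 under any scaling and array left out was -0.754 (largest SD 0.105). For the female-biased genes it cannot be told apart by the bound with arrays left out. Without chow array 3 their median went from 1.56 to 0.931 as deposited and from 1.34 to 0.754 with quantile normalization, above a bound of 0.5 by less than the largest SD of 0.3. With all arrays it stayed at 1.45, 1.34 and 1.35 with a common array median, quantile normalization and a common trimmed mean (camera adjusted p = 0.0434, 0.0126 and 0.0155). With the hybridization controls the call ended (adjusted p = 0.256), while the median went from 1.56 to 1.93 (SD 0.3 and 0.291). There the mean t statistic of members minus that of other genes, which camera compares, fell from 2.26 to 1.69. Lower growth hormone signalling may contribute but cannot be told apart: Igf1 and Igfals had log2 changes of -0.56 and -0.44 and Socs2, another target, one of 1.02, none past the threshold (adjusted p = 0.237, 0.335 and 0.0814). The diet itself stays open as an untested explanation.

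The 6 arrays can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 1045 probe sets and 877 genes against 0 and 0 in the highest other split, and 20 lists against 16. Every other split puts arrays of both diets in each group, so a diet difference adds to the spread within groups. Few or no gene calls would follow from that alone, so these counts do not measure chance.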

How the results depend on the processing

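The scalings to a common trimmed mean and to the hybridization controls were chosen after seeing the data, and all other alternatives before the data were examined. Of the 73 changed genes named, none reversed, 8 stayed past the threshold under every alternative run, 27 lost it only with the ordinary t statistic, 11 only with it or without a filter, and 27 elsewhere. For the differences below the cause was not tested, except that arrays left out or no filter change how many samples or genes are tested. Genes lower numbered 326 with quantile normalization, 277 with a common array median, 361 with a common trimmed mean and 212 with a filter at the 75th percentile of signal. Without a filter 178 probe sets and 256 genes changed (216 higher, 40 lower), with a trended robust prior 1872 and 1438 (1205, 233), with the ordinary t statistic 43 and 68 (67, 1), with array weights 5796 and 3503 (2936, 567), and scaled to the hybridization controls 5110 and 3911 (3818 higher). In the probe set fit with array weights ketogenic array 1 had a weight of 8.65 and the other arrays 0.386 to 1.97, so 1 array dominated the ketogenic group. Without probe sets that can bind several transcripts 622 probe sets changed. With the list correlation estimated, 0 lists were called. Leaving out 1 array gave 330 (ketogenic array 3) to 949 probe sets (chow array 1), 526 (ketogenic array 3) to 874 genes (chow array 1), 437 (ketogenic array 2) to 807 higher (chow array 1) and 60 (ketogenic array 3) to 143 lower genes, and 19 to 23 lists.

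Tests of lists that were not called reversed for lipoproteins (quantile normalization 0.554, fry 0.635), acute phase proteins (quantile normalization 0.597, without chow array 2 0.614, fry 0.702; over arrays left out the lowest adjusted p was 0.0671, without a reversal), glycolysis (stricter filter 0.955), insulin and IGF (fry 0.525) and the clock (fry 0.817). Genes not past the threshold whose log2 change reversed were Alb (quantile normalization 0.1425, array weights 0.02697, without chow array 3 0.02226, hybridization controls 0.3491), Acaca (array weights 0.0252, mean of probe sets 0.1802, without chow arrays 1 and 3 0.1089 and 0.054, without ketogenic arrays 1 and 3 0.07569 and 0.1146, hybridization controls 0.3444), Actb (without probe sets that can bind several transcripts -0.5173, mean of probe sets -0.1237), Ppargc1a (without chow array 2 0.1713, without ketogenic array 3 0.04097, hybridization controls 0.2306), Hspa5 (hybridization controls 0.1112) and Uqcrb (hybridization controls 0.07765). The lowest values over arrays left out, of the sign seen with all arrays, were -0.03453 for Alb, -0.243 for Acaca and -0.4043 for Ppargc1a. Signal over background limits the folds of genes with a mean log2 signal under that of the background of 10.8 in 1 diet to lower bounds. These bounds do not cover the spread between arrays.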

Other observations

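The gene families here were chosen after their values were seen, so only counts and values are given, and the test of a hypothesis that follows was chosen after too. Of 7 measured MHC class II genes, which present antigen, 5 rose, among them H2-Aa, H2-Eb1 and Cd74, whose signal went from 124.6 ± 38.85 to 594.4 ± 255 (SD, n = 3). Of 8 annexins, calcium-dependent membrane-binding proteins, 5 rose, with Anxa2 higher by 3.05 ± 0.30 (log2, SE). Of 23 collagens 9 rose, of 13 C-type lectins 6, of 8 S100 proteins 4 and of 15 tubulins 4. Several of these genes are also in the macrophage, matrix or blood lists.

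Of 5 terminal complement genes, whose proteins are made in hepatocytes, 3 fell, with log2 changes of -1.98 for C8b, -1.76 for C9 and -1.11 for C6. Of 56 cytochromes P450, 8 fell and 4 rose. Cyp2c29, Cyp2c70 and Cyp2d9 were among the falls, and Cyp2b9 and Cyp2b13 among the rises. The median of the cytochromes P450 was -0.321 as deposited and 0.0408 when scaled to the hybridization controls. Of 40 ribosomal protein genes 0 rose and 0 fell in limma (also 0 and 0 at an unadjusted p under 0.05), with a median of 0.132 as deposited and -0.0804 with a common trimmed mean.

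A hypothesis was that the rise of amino acid response genes came with general endoplasmic reticulum stress, which would raise the chaperones too. The chaperone list's median was -0.067, against 1.38 for the amino acid response genes, also with means under the background raised to it. Over the scalings, with all arrays and with each left out, it reached 0.427 at the highest, but minus the median of all genes it was -0.149 at the highest (largest SD over arrays left out 0.0574, SD over members 0.314), where general stress would need 0.5 or more. The measure was changed to this difference after the values were seen. The median itself lay under 0.5 by less than its largest SD over arrays left out, 0.115, and could not decide. General endoplasmic reticulum stress is thus argued against by the difference only. A response to amino acid supply may contribute and was not tested.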
